A study of Mus musculus with 12 samples.

How the data were processed

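Gene expression had been measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per culture, in fibroblasts from male C57BL/6J embryos. The 12 columns of the deposited table hold log2 summary signals per probe set, already brought to a common scale by the authors. Per the submitters' processing notes the tools were GCOS 1.4, Affymetrix Expression Console and PLIER, without a stated role. The method of normalization between arrays is not given in the sources used here. Column quantiles at 5, 25, 50, 75 and 95% differed by at most 0.08 between arrays, below the 0.1 set as the limit, so the deposited values were used as they stood, and correlations between arrays ran from 0.984 to 0.997. No genome build is named in the sources used here, so no positions are given.

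Of 28853 probe sets 21789 carried 1 gene symbol, 1621 several and 5443 none, according to the annotation table of the platform. Gene names were checked by gene ID against a RefSeq table of assembly GRCm38.p6, which left all symbols unchanged, and 8 list symbols were matched through a synonym. Of 642 entries in the gene lists 593 had a probe set of their own, and 49 were not analysed here. Each gene of a list was represented by its probe set with the highest mean.

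Comparisons, their tests, gene lists and most alternatives were chosen before the data were examined; those chosen later are named as such in the closing section. Groups followed the labels, and no array was left out. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (8 residual and 3.14 prior degrees of freedom). The contrasts were each knockout against its wild type, the difference and the mean of both knockout effects, and mTERT WT against mTR WT. Benjamini-Hochberg adjustment ran over all 28853 probe sets, with a threshold of 5%, and no filter on dim probe sets was used. The 30 gene lists covered telomerase, shelterin, DNA damage, p53, cell cycle, senescence, Wnt, Myc, NF-kB, interferon, metabolism and stress lists, fibroblast and other cell types, Hox and limb genes, ribosomal proteins and the neighbours of Tert and Terc. They were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of a contrast. Camera with an estimated correlation and fry served as alternatives. Members were also adjusted over the list alone, which does not correct for the other lists or contrasts.

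The genes named in the text were set by rule: Tert and Terc; the 12 probe sets of 1 gene with the highest and the 12 with the lowest moderated t in each knockout comparison; the 6 highest and 6 lowest in the other contrasts; and the members with the smallest p of each list that passed and of the telomere-related lists, up to 4 per list.

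The design text describes knockout and wild-type cultures as littermates, and the replicate numbers were tested as pairs on the 14426 brighter probe sets. In the mTERT line the deviations from the group mean correlated at 0.674, 0.733 and 0.790 for cultures of the same number, and between −0.525 and −0.184 for cultures of different numbers. The numbers were therefore taken to pair the mTERT cultures, from the data. Wild types of the same number in both lines correlated at 0.527, 0.135 and 0.132. Those of different numbers correlated between −0.320 and 0.179, with mTERT WT 2 and mTR WT 3 at 0.138 and mTERT WT 3 and mTR WT 2 at 0.179. Only number 1 stood apart, so these numbers were not taken as pairs. They were run as a block in an alternative chosen after the data were seen. The number of the pair accounted for 79.2% of the variance within the mTERT line and genotype for 8.49%, where 40% and 20% are expected by chance.

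Alternatives were the replicate number as a fixed or a random block, quantile normalization, median centring, removal of the dimmest or of all dimmer probe sets, restriction to probe sets of 1 gene, a trended and robust variance, array weights, a fit of the 6 arrays compared, a minimum fold of 1.5, and the omission of each array in turn. Where an omission left 2 arrays in a group, the pooled variance was used. Splits of the arrays into other groups were counted, all 10 for 3 against 3 and 100 drawn with seed 1 otherwise, with all 80 that part every mTERT pair added later. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

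The procedure was tested on simulated data with 28853 probe sets of independent noise, 200 of them changed. At log2 changes of 0.5, 1 and 2 it recovered 65.7, 94.0 and 98.5% for the mTERT comparison, 62.7, 92.5 and 98.5% for the mTR comparison, and 13.4, 80.6 and 97.0% for the difference of effects. It recovered 83.6, 92.5 and 98.5% for the mean effect and 59.7, 91.0 and 98.5% for the wild types. False calls numbered 9, 5, 7, 10 and 15 in that order. A list of 20 genes shifted by 0.3 was called in each comparison, and 0 other lists were. With independent noise the genes of a list were uncorrelated, so this count cannot show the rate of false list calls in the real arrays. The simulation held no shifts shared by a litter. Its noise was drawn from the moderated variances, and the 200 changed probe sets eased the adjusted threshold. In the real mTR comparison the smallest adjusted p with limma was 0.452. The recovered shares can therefore not be read as the power reached in these data. With 3 arrays per group the number of arrays limits the precision. Of the observed differences, 95% were smaller in size than 0.20 in the mTERT, 0.32 in the mTR and 0.34 in the wild-type comparison. These values mix noise, shifts between cultures and any effects, and are not error limits.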

Results

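The deposited table held log2 signals of 28853 probe sets in 12 cultures of mouse embryonic fibroblasts at passage 5, 3 cultures in each of 4 groups. The groups were fibroblasts lacking telomerase reverse transcriptase (mTERT KO), their wild-type counterparts (mTERT WT), fibroblasts lacking the telomerase RNA (mTR KO) and their wild-type counterparts (mTR WT). All knockouts were of the first generation without telomerase. Differences below are log2 values, knockout minus wild type unless stated, ± standard error of the limma fit, with n = 3 arrays per group. The Y-linked genes Eif2s3y, Kdm5d and Uty were expressed in every culture, and Xist lay between 3.93 and 4.19, so no culture departed from the male label.

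Tert, the gene of the reverse transcriptase, was lower in each mTERT KO culture than in any other culture. Its signal was 5.72, 5.74 and 5.51 in mTERT WT cultures 1 to 3 and 4.99, 4.84 and 4.75 in mTERT KO cultures 1 to 3. In the mTR line it read 5.79, 5.70 and 5.66 in wild type and 5.80, 5.69 and 5.80 in the knockout. Tert fell by 0.79 ± 0.08 in the mTERT comparison (limma, adjusted p = 0.0352). With the 2 knockout cultures that lay below the 95th percentile of olfactory receptor probe sets placed at that percentile, the difference was at least 0.64 in size, and 0.70 against the 9 other cultures. The call ended after quantile normalization (0.0504), with only the 6 arrays compared, and without mTERT WT 1 (0.347), mTERT WT 2 (0.333), mTERT KO 2 (0.337) or mTERT KO 3 (0.280), while the difference stayed between −0.87 and −0.74. With all same-numbered cultures of both lines as a block the adjusted p was 0.134, and with the mTERT pairs alone as a block it was 0.0187. Against all 9 other cultures the difference was −0.85 (exact permutation p = 0.00455), while the exact p within the line was 0.1, the smallest that 3 against 3 can give. Both exact tests treat the cultures as exchangeable and ignore the mTERT pairs, so neither p is exact for this design. In the mTR comparison Tert differed by 0.05 ± 0.08 (adjusted p = 0.928).

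Terc, the gene of the telomerase RNA, read 4.65, 4.73 and 4.94 in mTR WT and 4.50, 4.73 and 4.57 in mTR KO cultures. It read 4.67, 4.82 and 4.94 in mTERT WT and 4.77, 4.64 and 4.86 in mTERT KO cultures. The mTR difference was −0.17 ± 0.10 (limma, p = 0.119, adjusted p = 0.840), with an exact p of 0.2 within the line and of 0.0545 against the 9 other cultures. In none of the 9 cultures with an intact Terc gene did its signal pass the 95th percentile of the 1035 olfactory receptor probe sets, which served as a measure of background. Tert passed that level in 9 of 9 cultures with an intact Tert gene and in 1 of 3 mTERT KO cultures. The array therefore carried a visible mark of the Tert knockout and none of the Terc knockout.

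**Figure D1:**
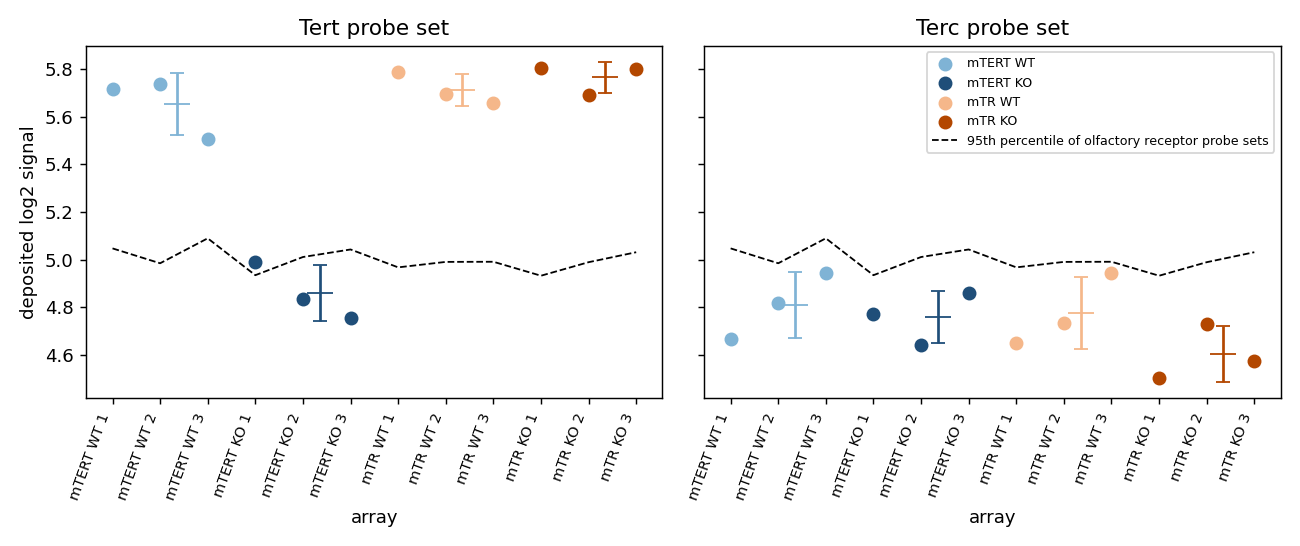
Signal of the Tert and the Terc probe set in every array. Points are single arrays, the bars beside them give the mean and the standard deviation of each group of 3, and the dashed line is the 95th percentile of the olfactory receptor probe sets in that array.

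Apart from Tert, no gene passed the test between mTERT KO cultures and their wild type. Of 28853 probe sets, Tert alone passed a 5% false discovery rate, 553 had an unadjusted p below 0.05 with limma, 277 of them higher and 276 lower. The other 3 splits of these 6 cultures that part every pair gave 632, 600 and 897. Uniform p values would give 1443, and with the mTERT pairs as a block there were 681. The test was thus conservative in this paired line, and a paired fit of the mTERT cultures alone was not run. Few calls are therefore no evidence that effects were absent. The 12 genes at the upper end of the ranking did not pass the test (adjusted p = 1 for each), and each was higher in all 3 knockout cultures than in all 3 wild types. Developmental regulators were among them: Zic1, a zinc-finger factor of neural and axial development, differed by 0.89 ± 0.24, and Hoxd12, a limb patterning gene, by 0.55 ± 0.16. Scn7a, a sodium channel gene, differed by 0.75 ± 0.22, Tsen15, a subunit of the tRNA splicing endonuclease, by 0.61 ± 0.16, and Spon2, a secreted matrix protein, by 0.56 ± 0.17. The others were Fam43a (0.52 ± 0.13), Zfp788 (0.45 ± 0.13), Ahrr, the aryl hydrocarbon receptor repressor (0.33 ± 0.10), Rnf151 (0.29 ± 0.08), Brf2, a factor of RNA polymerase III (0.25 ± 0.08), Tsr2 (0.21 ± 0.06) and Lpcat2b (0.18 ± 0.05). Lpcat2b read at most 4.43 in any culture, below the background level used for Terc.

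At the lower end, behind Tert, stood Fgf10, a growth factor of limb and lung outgrowth, at −0.96 ± 0.23, and Arsk, an arylsulfatase, at −0.68 ± 0.17. Ppp1r1a, an inhibitor of protein phosphatase 1, differed by −0.35 ± 0.08, Msrb2, a methionine sulfoxide reductase, by −0.29 ± 0.08, and Ndufs6, a subunit of respiratory complex I, by −0.28 ± 0.06. Cbx7, a Polycomb protein, differed by −0.22 ± 0.06, Plppr4 by −0.26 ± 0.07 and Mpo, the myeloperoxidase gene, by −0.23 ± 0.07. Plppr4 and Mpo read below the background level used for Terc in every culture. The odorant receptor genes Olfr120 (−0.28 ± 0.07), Olfr64 (−0.26 ± 0.06) and Olfr1 (−0.24 ± 0.06) had group means between 4.02 and 4.57, at the level of other odorant receptors. None of these 11 passed the test (adjusted p = 1). Across all probe sets 5.97% had groups that did not overlap, and the other 3 splits that part every pair gave 6.55, 5.98 and 7.78%. The 10% that chance gives for unpaired cultures does not apply to these pairs.

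In the full fit the lists closest to telomerase did not pass in mTERT KO cultures, with medians between −0.08 and 0.05. No gene list passed a 5% false discovery rate with camera there, and 6 lists had an unadjusted p below 0.05. The outcome depended on single arrays: 11 lists passed without mTERT WT 1, 6 without mTERT KO 2, and at most 2 without any other. DNA damage response genes passed upward without mTERT WT 1 (adjusted p = 0.00796) or mTERT KO 3 (0.0038). Cell cycle genes passed upward without mTERT WT 1 (0.00796). Senescence genes passed downward without mTERT WT 1 (0.0283) or mTERT KO 2 (0.0485). The values below are those of the full fit. Among 14 telomerase and assembly genes the median was 0.04, the mean −0.02 and the test pointed down (adjusted p = 0.893); adjusted over the list alone, Tert was lower and no other member passed, with Nop10 at 0.19 and Pinx1 at 0.13. The 14 shelterin and telomere maintenance genes had a median of 0.05 (adjusted p = 0.269; Terf1 at 0.14), and 34 DNA damage response genes a median of 0.04 (adjusted p = 0.205; Xrcc5 at 0.20, Xrcc1 at 0.17). The 25 p53 targets had a median of −0.03 (adjusted p = 0.708; Fas at −0.27, Mdm2 at −0.14, Btg2 at 0.17), and the 37 cell cycle genes a median of 0.05 (adjusted p = 0.312; E2f2 at −0.20). For 24 senescence genes the median and the mean were both 0.02 while the test pointed down (adjusted p = 0.673). Wnt and beta-catenin targets had a median of −0.08 (adjusted p = 0.205). No member of these 6 lists passed when adjusted over its list alone.

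The contractile genes of smooth muscle and myofibroblasts lay lower in mTERT KO cultures for 11 of 11 members, with a median of −0.12, and did not pass (adjusted p = 0.101). With all same-numbered cultures as a block their adjusted p was 0.0116, with the mTERT pairs alone as a block 0.0652, and 0.948 with an estimated correlation. Interferon-stimulated genes had a median of −0.21 (adjusted p = 0.586) and macrophage markers one of −0.13 (adjusted p = 0.673), with 15 of 16 markers lower.

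**Figure D2:**
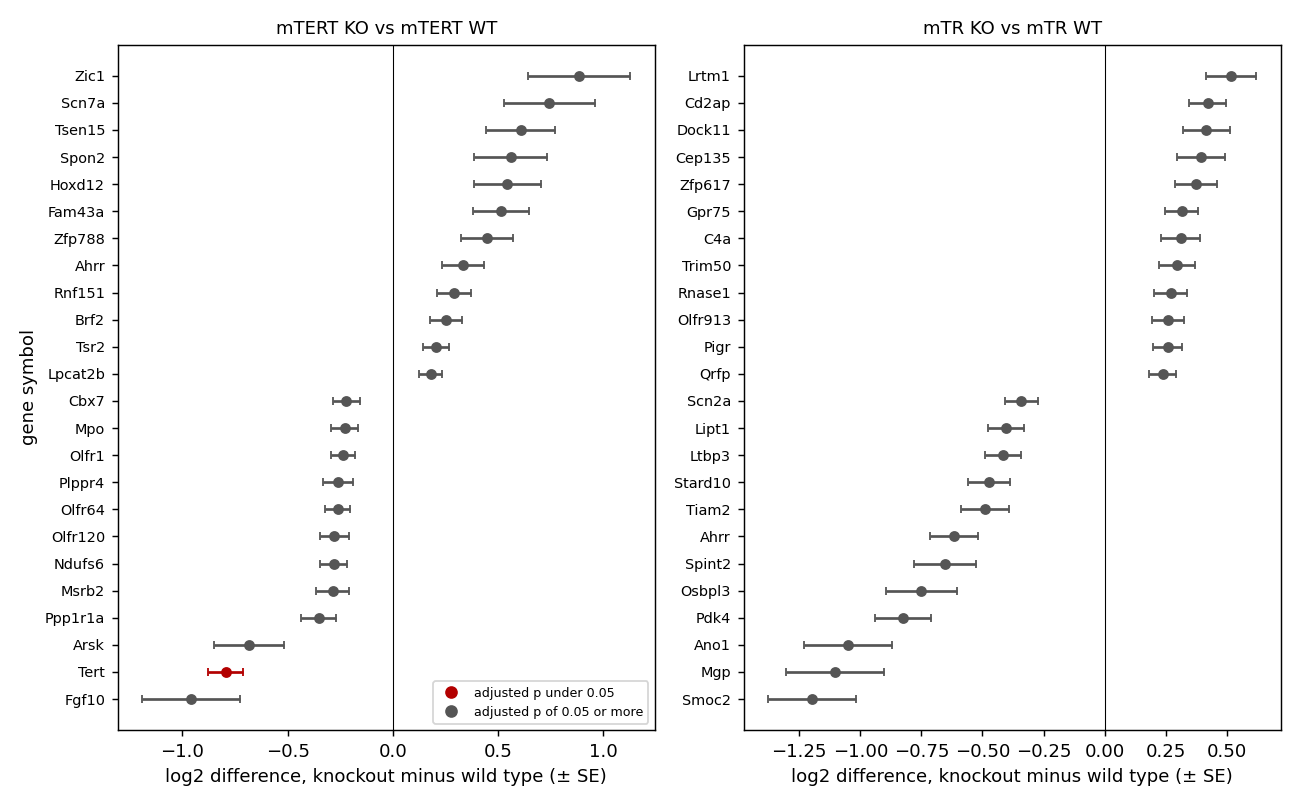
Log2 differences, knockout minus wild type, of the 12 genes with the highest and the 12 with the lowest moderated t in each knockout comparison. Bars are standard errors of the limma fit with 3 arrays per group, and red marks an adjusted p below 0.05.

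In the mTR line no single gene passed the test, and the genes at the lower end of the ranking showed larger differences than those of the mTERT line. Smoc2, a matricellular protein, differed by −1.20 ± 0.18, Mgp, the matrix Gla protein that inhibits calcification, by −1.10 ± 0.20, and Ano1, a calcium-activated chloride channel, by −1.05 ± 0.18. Pdk4, a kinase that inhibits pyruvate dehydrogenase, differed by −0.83 ± 0.11, Osbpl3, an oxysterol-binding protein, by −0.75 ± 0.15, Spint2, a serine protease inhibitor, by −0.65 ± 0.13, and Ahrr by −0.62 ± 0.10. The others were Tiam2 (−0.49 ± 0.10), Stard10 (−0.47 ± 0.09), Ltbp3, a latent TGF-beta binding protein (−0.41 ± 0.07), Lipt1 (−0.40 ± 0.07) and Scn2a (−0.34 ± 0.07). The smallest adjusted p was 0.452, shared by Pdk4, Smoc2 and Ahrr, and for each of the 12 the groups did not overlap. For all of the 12 but Lipt1, every mTR WT culture also lay above every mTERT culture. Ano1, for example, read 6.04, 5.69 and 6.01 in mTR WT cultures and at most 5.39 in any other culture. Lipt1 read 6.37 in mTERT WT 1 and 6.35 in mTR WT 3. These differences can therefore not be assigned to the knockout rather than to a shift of the mTR WT cultures.

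Genes at the upper end in mTR KO cultures had smaller differences. Lrtm1 differed by 0.52 ± 0.10, Cd2ap, an adaptor of the actin cytoskeleton, by 0.42 ± 0.08, Dock11, an exchange factor for Cdc42, by 0.42 ± 0.10, and Cep135, a centriole protein, by 0.39 ± 0.10. Zfp617 (0.37 ± 0.09), Gpr75 (0.31 ± 0.07), C4a (0.31 ± 0.08), Trim50 (0.29 ± 0.07), Rnase1 (0.27 ± 0.07), Olfr913 (0.26 ± 0.06), Pigr (0.26 ± 0.06) and Qrfp (0.24 ± 0.05) followed. None passed (adjusted p of 0.560 for Cd2ap, 0.804 for Lrtm1 and 0.839 for the other 10). C4a, Trim50, Rnase1, Olfr913, Pigr and Qrfp read at most 4.79 in any culture. The background level used for Terc was at least 4.93 in each array, so these genes lay within background. Of 28853 probe sets, 0 passed with limma and 1679 had an unadjusted p below 0.05, 644 higher and 1035 lower. Other splits of these cultures gave between 663 and 1865 such p values, so 1679 is no surplus over regrouping. The groups did not overlap for 11.4% of probe sets, against 10% by chance, and this share was not counted in other splits.

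Lists of innate immunity had the largest medians of the mTR comparison. All 23 interferon-stimulated genes were higher in mTR KO cultures, with a median of 0.73 (camera, adjusted p = 2.61e-05), among them Oas2 (0.81 ± 0.46), Eif2ak2, the double-stranded RNA sensing kinase (0.73 ± 0.37), Rsad2 (0.48 ± 0.23) and Oasl1 (0.26 ± 0.13). All 16 macrophage markers were higher, with a median of 0.72 (adjusted p = 0.00195), among them Mrc1 (1.43 ± 0.97), C1qb (0.83 ± 0.68), Ptprc (0.80 ± 0.58) and Lyz2 (0.61 ± 0.53). The mean macrophage signal was 6.72, 8.25 and 8.74 in mTR WT cultures 1 to 3 and 9.53, 8.84 and 7.52 in mTR KO cultures 1 to 3. NF-kB targets had a median of 0.18 and did not pass (adjusted p = 0.0714, or 0.0136 with the mTERT pairs as a block). The adjusted p was 0.939 with an estimated correlation for each of these lists, and no member passed when adjusted over its list alone. Without mTR KO 1 the adjusted p was 0.241 for the interferon list and 0.447 for the macrophage list, and without mTR WT 1 it was 0.797 for the macrophage list.

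All 14 measured cholesterol synthesis genes were higher, with a median of 0.20 (adjusted p = 2.61e-05), among them Stard4 (0.53 ± 0.23), Insig1 (0.34 ± 0.15), Hmgcs1 (0.33 ± 0.16) and Msmo1 (0.26 ± 0.11). Of 37 cell cycle genes 35 were higher, with a median of 0.13 (adjusted p = 0.000783; Cenpe 0.52 ± 0.30, Mki67 0.46 ± 0.31, Bub1 0.40 ± 0.26, E2f2 0.27 ± 0.09). Of 34 DNA damage response genes 28 were higher, with a median of 0.11 (adjusted p = 0.00904; Blm 0.33 ± 0.15, Clspn 0.26 ± 0.13, Palb2 0.19 ± 0.09, Atr 0.15 ± 0.08). All 3 lists had an adjusted p of 0.939 with an estimated correlation, and no member passed when adjusted over its list alone. Without mTR KO 1 the cholesterol list had an adjusted p of 0.241, and the cell cycle and DNA damage lists turned downward (adjusted p = 0.241 and 0.857); without mTR WT 2 the cell cycle list had 0.0661.

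All 11 smooth muscle and myofibroblast genes were lower, with a median of −0.30 (adjusted p = 0.000161), among them Myh11, the smooth muscle myosin heavy chain (−0.997 ± 0.49), Lmod1 (−0.42 ± 0.20), Synpo2 (−0.39 ± 0.21) and Myl9 (−0.30 ± 0.18). Of 37 Hox genes 24 were lower, with a median of −0.15 (adjusted p = 0.00420), the distal genes Hoxd13 (−1.43 ± 0.57), Hoxd11 (−0.74 ± 0.26), Hoxa13 (−0.62 ± 0.15) and Hoxa9 (−0.47 ± 0.15) among them. Limb and body position regulators had a median of −0.20 (adjusted p = 0.0230; Foxc1 −0.79 ± 0.27, Lhx9 −0.73 ± 0.28, Foxf1 −0.44 ± 0.16, against Shox2 at 0.68 ± 0.23). Cartilage and bone markers had a median of −0.05 (adjusted p = 0.0142; Col2a1 −0.79 ± 0.27, Col11a1 −0.59 ± 0.18, Hapln1 −0.52 ± 0.22, Ibsp −0.31 ± 0.11). All 4 had an adjusted p of 0.939 with an estimated correlation, and no member passed when adjusted over its list alone. Without mTR KO 1 the adjusted p was 0.241 for smooth muscle, 0.418 for Hox and 0.123 for cartilage genes, and without mTR WT 1 it was 0.487 for the cartilage and for the limb list. The limb list also lost its call without mTR KO 2 (0.193) or mTR KO 3 (0.216), and the Hox list without mTR WT 2 (0.0626). Without mTR KO 2 the differences were −0.75 for Hoxd13, −0.42 for Hoxd11 and −0.45 for Lhx9. Of the 36 members named from the 9 lists that passed in this comparison, 26 differed from the full set by a factor above 1.5 when some single array was left out, and 0 reversed. These members were picked by small p in the same data, so keeping their direction was largely given in advance. The same holds for such counts in the contrasts below.

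Of the 7 lists tied to telomere function, cell cycle and DNA damage response passed in the mTR comparison, with the limits given above, and the other 5 did not. The telomerase list had a median of −0.02 and a mean of −0.01 while the test pointed up (adjusted p = 0.996; Nop10 −0.32 ± 0.16, Nvl 0.17 ± 0.10, Gar1 0.15 ± 0.10). Shelterin genes had a median of 0.02 (adjusted p = 0.803; Dclre1b 0.16, Stn1 0.12, Ten1 −0.12, Terf2ip −0.11). The p53 targets had a median of −0.04 (adjusted p = 0.578; Fas −0.50 ± 0.23, Perp −0.37 ± 0.16, Phlda3 −0.20, Rrm2b 0.15), senescence genes one of 0.04 (adjusted p = 0.798; Hgf 0.49, Plau −0.24, Icam1 0.22, Igfbp7 −0.17), and Wnt targets one of 0.04 with a mean of −0.002 (adjusted p = 0.883; Bmp4 −0.91 ± 0.53, Apcdd1 −0.23).

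**Figure D3:**
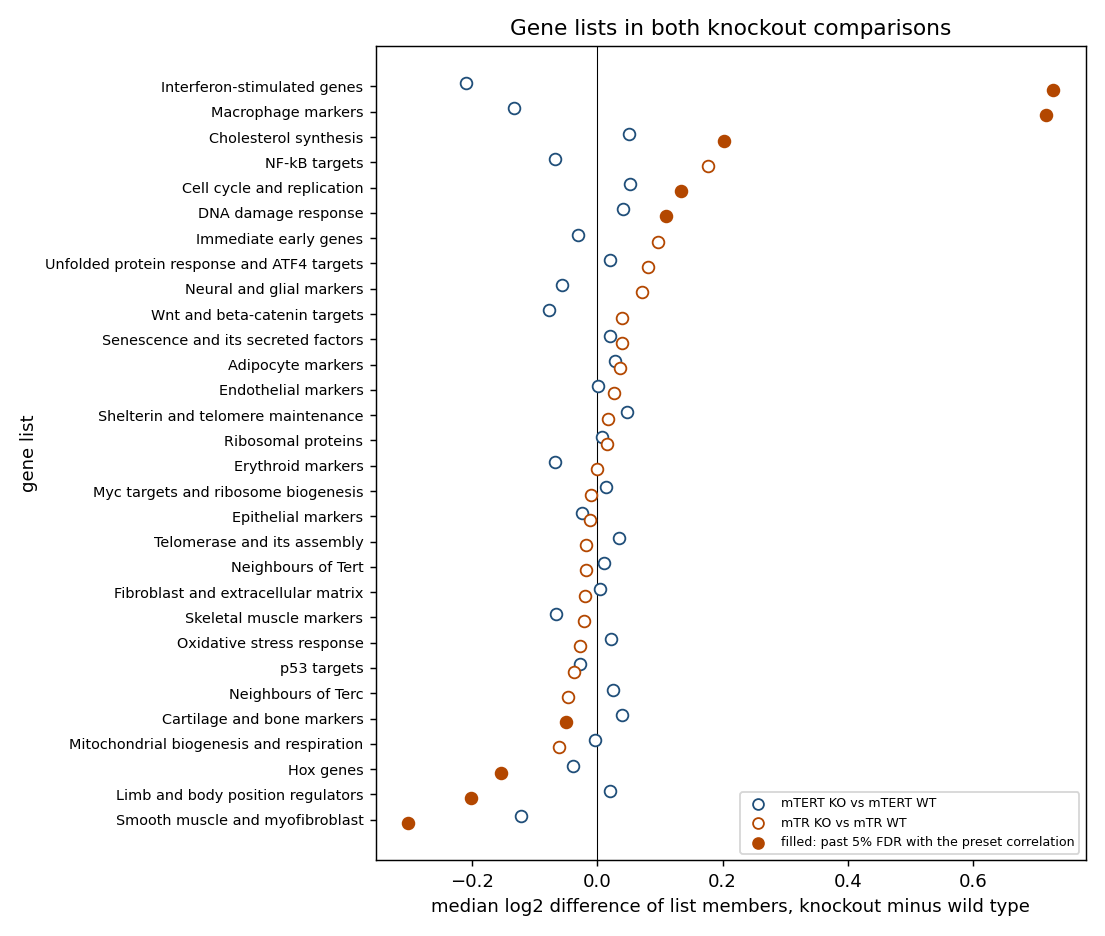
Median log2 difference of the measured members of each gene list in the mTERT comparison (blue) and the mTR comparison (orange). Filled points passed a 5% false discovery rate with camera and its preset correlation, and none passed with an estimated correlation.

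The lists of other tissues and functions did not pass in the full fit of either knockout comparison. In the order mTERT, then mTR, the adjusted p was 0.706 and 0.928 for Myc targets and ribosome biogenesis, 0.824 and 0.346 for mitochondrial biogenesis, 0.806 and 0.631 for oxidative stress, 0.673 and 0.255 for the unfolded protein response, and 0.673 and 0.768 for immediate early genes. It was 0.691 and 0.578 for fibroblast and matrix genes, 0.205 and 0.803 for skeletal muscle, 0.853 and 0.798 for adipocyte, 0.979 and 0.768 for epithelial and 0.673 and 0.803 for endothelial markers. It was 0.205 and 0.883 for erythroid, 0.205 and 0.578 for neural and glial markers, and 0.809 and 0.578 for ribosomal proteins. The neighbours of Tert had 0.878 and 0.578, with 1 member lower in each line when adjusted over the list alone, and the neighbours of Terc 0.323 and 0.576. In the mTERT comparison cholesterol synthesis had 0.269, NF-kB targets 0.312, cartilage and bone markers 0.673, Hox genes 0.514 and limb regulators 0.893.

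The knockout effects of both lines were compared directly. Tert had a more negative effect in the mTERT line by 0.85 ± 0.12, as did Gal3st2c (−0.46 ± 0.11), Cd2ap (−0.43 ± 0.11), Zp3 (−0.38 ± 0.09), Olfr913 (−0.36 ± 0.09) and Ankrd34b (−0.31 ± 0.08). Of these, Gal3st2c, Zp3, Olfr913 and Ankrd34b read below the background level used for Terc in every culture. Smoc2 (1.63 ± 0.25), Scx, a transcription factor of tendon progenitors (1.29 ± 0.30), Hoxa13 (1.08 ± 0.21), Ahrr (0.95 ± 0.14), Pdk4 (0.87 ± 0.16) and Plaat3 (0.62 ± 0.13) had a more positive effect in the mTERT line. No probe set passed with limma (smallest adjusted p 0.404), and 965 had an unadjusted p below 0.05.

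Of the gene lists, 6 differed between the knockout effects with the preset correlation. The mTERT effect was lower for interferon-stimulated genes (median −0.89, adjusted p = 7.48e-05; Eif2ak2 −0.82 ± 0.53), macrophage markers (−0.86, 0.00782; Mrc1 −1.42 ± 1.37), cholesterol synthesis (−0.18, 0.0207; Stard4 −0.48 ± 0.33) and NF-kB targets (−0.23, 0.0221; Il1b −0.35 ± 0.12). It was higher for cartilage and bone markers (0.35, 0.0207; Col2a1 1.08 ± 0.38) and Hox genes (0.09, 0.0125). Adjusted over the list alone, 5 Hox genes passed: Hoxd13 (2.80 ± 0.81), Hoxd11 (1.51 ± 0.37), Hoxd10 (1.46), Hoxa13 and Hoxd12 (0.87 ± 0.22). With an estimated correlation the adjusted p of each list was 0.909. Without mTR KO 1 none of the 6 passed: the adjusted p was 0.129 for interferon, 0.306 for macrophage, 0.201 for NF-kB, 0.836 for cholesterol, 0.0739 for cartilage and 0.335 for Hox genes. Other arrays ended calls as well. Of 12 fits with 1 array left out, interferon genes passed in 9, cartilage and Hox genes in 8, macrophage and cholesterol genes in 7, and NF-kB targets in 5. Of 24 members with the smallest p in these 6 lists, 17 differed by a factor above 1.5 when some single array was left out, and 0 reversed; Mrc1 was at −0.55 without mTR KO 1. With same-numbered cultures as a block, cell cycle genes (0.0349) and limb regulators (0.0338) passed as well; with the mTERT pairs alone as a block they did not (0.136 and 0.0625).

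The mean of both knockout effects gave no single gene past the test (limma, smallest adjusted p 0.985), with 1180 unadjusted p values below 0.05. Tert (−0.37 ± 0.06), Mgp (−0.71 ± 0.14), Ano1 (−0.64 ± 0.13), Pdk4 (−0.39 ± 0.08), Emilin1, an elastic fibre protein (−0.26 ± 0.05) and Ndufs6 (−0.24 ± 0.05) stood at the lower end. Tert was lower only in the mTERT line and Pdk4 only in the mTR line, and the others were lower on average in both. Pdk4 read 6.36, 6.34 and 6.34 in mTERT WT and 6.16, 6.54 and 6.47 in mTERT KO cultures. Dock11 (0.30 ± 0.07), Zfp617 (0.27 ± 0.06), Ifi208 (0.25 ± 0.06), Gpr75 (0.23 ± 0.05), Il9 (0.21 ± 0.05) and Rab33a (0.18 ± 0.04) stood at the upper end. Il9 and Rab33a read below the background level used for Terc in every culture. Smooth muscle genes were lower for 11 of 11 members (median −0.23, adjusted p = 2.26e-05), with Myh11 at −0.75 ± 0.35 and Lmod1 at −0.34 ± 0.14. Higher lists were cholesterol synthesis (0.15, 3.10e-05; Cyp51 0.30 ± 0.15), cell cycle (0.09, 0.000742; Bub1 0.27 ± 0.18), DNA damage response (0.06, 0.00168; Blm 0.26 ± 0.10) and interferon-stimulated genes (0.27, 0.00952; Dhx58 0.40 ± 0.35). The lines had opposite signs for the interferon list, with 19 of 23 genes lower in mTERT KO (median −0.21) and 23 of 23 higher in mTR KO cultures (0.73). The adjusted p of all 5 lists was 0.949 with an estimated correlation. Macrophage markers (median 0.30) did not pass (0.103), and with the mTERT pairs alone as a block they did (0.0492). Only the smooth muscle list passed in each of the 12 fits that left out 1 array, and without mTR KO 1 the adjusted p was 0.0764 for cholesterol synthesis, 0.959 for cell cycle, 0.669 for DNA damage and 0.957 for interferon genes, with the cell cycle list turned downward. Of the 20 members with the smallest p in the 5 lists, 17 differed by a factor above 1.5 when some single array was left out, and 0 reversed. Without mTR KO 1 Bub1 was at 0.12, Dhx58 and Blm at 0.16 and Myh11 at −0.47. Across probe sets the knockout effects correlated with r = 0.08, and 65 of 100 random regroupings within the lines gave an r at least as large in size, as did 36 of the 80 that part every mTERT pair.

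Between the wild-type cultures of the lines 5 probe sets passed, against 1 and 0 in the knockout comparisons. Relative to mTR WT, mTERT WT cultures were higher in Raet1d, an NKG2D ligand (1.17 ± 0.14), and lower in Smoc2 (−1.44 ± 0.18), Hoxa13 (−1.21 ± 0.15) and Ahrr (−0.84 ± 0.10), each at an adjusted p of 0.0416. A further probe set that passed carried several gene symbols, so that 1 was higher and 4 were lower. With the number of the wild types as a block 2 passed, Hoxa13 and Gldn (0.0359 each), and 1 of these was among the 5; the adjusted p was 0.0514 for Ahrr and 0.0828 for Smoc2 and Raet1d. Nrk (1.09 ± 0.16), Tbx1 (0.68 ± 0.10), Fdft1 (0.54 ± 0.11), Msmo1 (0.54 ± 0.11), Pced1b (0.32 ± 0.07), Gldn (−1.16 ± 0.16), Pdk4 (−0.73 ± 0.11) and Tiam2 (−0.72 ± 0.10) did not pass without the block. With limma 1956 unadjusted p values lay below 0.05, and the groups did not overlap for 13.1% of probe sets, against 9.74, 8.28 and 9.14% in the other 3 splits that part every number. After quantile normalization no probe set passed, and leaving out single arrays gave between 0 and 11.

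Cholesterol synthesis had the smallest list p between the wild types: 14 of 14 genes were higher in mTERT WT, with a median of 0.48 (adjusted p = 3.27e-13), and 9 passed when adjusted over the list alone, among them Insig1 (0.62 ± 0.15), Hmgcs1 (0.57 ± 0.16), Fdft1 and Msmo1. Its adjusted p was 0.634 with an estimated correlation. Also higher were interferon-stimulated genes (0.78, 1.83e-05; Oas2 0.82 ± 0.46), macrophage markers (0.79, 0.00149; C1qa 1.11 ± 0.78), cell cycle genes (0.15, 0.000433; Cenpe 0.47 ± 0.30), NF-kB targets (0.27, 0.00175; Vcam1 0.67 ± 0.28) and skeletal muscle markers (0.09, 0.0253; Myog 0.33 ± 0.11). Lower were cartilage and bone markers (−0.11, 0.0215; Col2a1 −0.90 ± 0.27), fibroblast and matrix genes (−0.10, 0.0228; Mfap5 −0.71 ± 0.22) and limb regulators (−0.12, 0.0421; Lhx9 −0.98 ± 0.28, Msx2 −0.87 ± 0.22, Tbx18 −0.85 ± 0.21), of which these 3 passed over the list alone. With an estimated correlation the adjusted p of these 8 lists was 0.874. Without mTERT WT 2 only the cholesterol and cell cycle lists passed: the adjusted p was 0.213 for interferon, 0.545 for NF-kB, 0.0659 for macrophage, matrix and skeletal muscle, 0.0888 for cartilage and 0.103 for limb genes. Without mTR WT 1 the macrophage list had 0.578, and without mTERT WT 1 the cell cycle list had 0.108. Matrix, skeletal muscle and limb lists each passed in only 2 of the 6 fits with 1 array left out. Without mTERT WT 3 the adjusted p was 0.520 for matrix and 0.295 for skeletal muscle genes. Without mTR WT 1 it was 0.499 for limb and for cartilage genes. Of 36 members with the smallest p in the 9 lists, 17 differed by a factor above 1.5 when some single array was left out, and 0 reversed; C1qa was at 0.36 without mTR WT 1. The Hox list did not pass (median 0.08, mean −0.08, test pointing down, adjusted p = 0.536). Adjusted over the list alone, 8 of its genes were lower in mTERT WT, all of them Hoxa or Hoxd genes of the groups 9 to 13: Hoxd13 (−2.12), Hoxd10 (−1.51), Hoxd11 (−1.34), Hoxa11 (−1.24), Hoxa13 (−1.21), Hoxa10 (−0.81), Hoxa9 (−0.64) and Hoxd12 (−0.57). Of these, only Hoxa13 passed over all probe sets. Hoxd13 read 4.99, 6.67 and 6.65 in mTERT WT cultures 1 to 3. Line and the cultures' origin cannot be separated in this comparison, since each line had its own wild type. The mTR comparison shares the mTR WT cultures with it. Interferon, macrophage, cholesterol, cell cycle, cartilage and limb lists passed in the same direction relative to mTR WT in both. The smooth muscle, DNA damage and Hox lists passed in the mTR comparison and not here.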

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

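The counts of other splits, the test of macrophage content and the test of a single array were chosen after the results were seen. A test of the difference between the knockout effects of both lines picked out 6 gene lists. The median of the mTERT effect minus the mTR effect was −0.89 for interferon-stimulated genes, −0.86 for macrophage markers, −0.23 for NF-kB targets and −0.18 for cholesterol synthesis. It was 0.35 for cartilage and bone markers and 0.0906 for Hox genes. With an estimated correlation none of the 6 passed (adjusted p = 0.909).

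The immune lists were weighed between macrophages in the cultures, a single array and the genotype. Across cultures the interferon list correlated with the macrophage list at r = 0.455 in the 6 wild types and 0.636 in the 6 knockouts (permutation p = 0.368 and 0.200). The test thus left a difference in macrophage content open. Each set pools both lines, whose wild types differed in both lists in the same direction, so line could contribute to r. The p values ignore line, and the mTERT pairs make the wild-type and knockout sets dependent. Without mTR KO 1 the adjusted p of the interferon list in the mTR comparison was 0.241, and without any other array it was at most 0.0459, so 1 array decided that call. With the macrophage mean as a covariate and the preset correlation the interferon list still passed in the mTR comparison (camera, adjusted p = 0.0254) and not in the difference of effects (0.0569). With an estimated correlation and no covariate, 0 lists passed in the mTR comparison. An effect of losing the telomerase RNA could not be told apart from the history of 1 culture (0.241). A shift of the mTR WT cultures was not weighed, and the interferon list was also higher in mTERT WT than in mTR WT.

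Other divisions of the same arrays were counted. For 3 against 3 there are 10 splits, too few for a share under 0.05. In the mTR comparison 9 lists passed, the highest other split gave 14, and 7 of 10 splits gave at least as many; 0 probe sets passed, and at most 1 in another split. In the mTERT comparison 1 probe set passed in the real split and 0 in every other (1 of 10). There 0 lists passed, and the highest other split gave 13. The 3 other splits that parted all 3 pairs gave 0, 0 and 1 lists, and those that kept pairs together gave 7 to 13, which points to the structure of the samples.

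For the wild types 5 probe sets passed against 0 in any other split (1 of 10), and 9 lists against at most 13 (4 of 10). The 3 other splits that parted every wild-type number gave 0 probe sets each and 8, 4 and 3 lists. For the difference of effects 74 of 100 splits gave at least the 6 lists found, up to 15; 0 probe sets passed, and at most 3 in another split. For the mean effect 82 of 100 gave at least the 5 lists found, up to 15; 0 probe sets passed, and at most 17 in another split. Where 0 passed, every split gives at least as many (10 of 10 or 100 of 100), so these shares test nothing. Since the mTERT cultures are paired, all 80 splits that part every mTERT pair were also counted. Of these 48 gave at least 6 lists for the difference, up to 14, and 63 at least 5 for the mean effect, up to 14, so that chance was not excluded for the list counts of either contrast.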

How the results depend on the processing

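No named gene reversed in 962 runs on 83 results: 931 kept direction and side of the threshold, 27 were weaker and 4 stronger. These genes were picked as the extremes of the same data, and most lay far from the threshold in the full fit. Keeping direction and side was therefore largely given in advance, and the tally is no test of robustness. Tert stayed negative throughout: −0.80 after quantile normalization (adjusted p = 0.0504) and −0.87 to −0.74 with 1 array left out, past the threshold only without mTERT WT 3 or mTERT KO 1. The mTERT count of 1 probe set became 0 after quantile normalization or with only the 6 arrays compared, and ran from 0 to 2 with 1 array left out. The mTR count ran from 0 to 3, with 3 without mTR WT 2, and the mean effect from 0 to 1, with 1 without mTERT KO 1. The wild-type count of 5 became 0 after quantile normalization, 9 with array weights, 1 with only the 6 arrays, and 0 to 11 with 1 array left out. The cause was not tested, apart from the smaller samples.

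The lists depended on the correlation assumed: the mTR count of 9, the difference count of 6, the mean count of 5 and the wild-type count of 9 all became 0 with an estimated correlation or with fry. With 1 array left out the list counts ran from 0 to 11 for mTERT (11 without mTERT WT 1, 6 without mTERT KO 2), 1 to 10 for mTR (1 without mTR KO 1), 2 to 9 for the difference, 2 to 8 for the mean effect and 2 to 12 for the wild types. Without the dimmer probe sets 1 mTERT list passed, smooth muscle, and the cartilage (0.152) and limb (0.314) calls of the mTR comparison were lost. The correlation of the knockout effects, 0.08, ran from −0.10 to 0.23 with 1 array left out and turned negative without mTERT KO 2 (−0.1034), mTERT WT 1 (−0.0108) or mTERT WT 3 (−0.0105).

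With the replicate number as a block in both lines Tert kept its difference of −0.79 (adjusted p = 0.134), so the mTERT count was 0 probe sets, and 1 mTERT list passed. Beyond the calls given in the report, the mTERT pairs and the wild-type numbers as blocks changed none. The mTR cultures shared only a number: same-numbered cultures correlated at −0.156, 0.289 and −0.377, and not every culture correlated best with its own number, since mTR KO 1 did so with mTR WT 3 (0.372) and mTR KO 3 with mTR WT 1 (0.319). Whether the mTR numbers follow litters is therefore open, and so is what this block removes there. The block left the mTR count at 0 while the unadjusted count moved from 1679 to 2451. As a random block the consensus correlation was 0.171. With the number of the wild types as a block the wild-type count was 2 in place of 5, 1 of them shared, and all 9 lists passed.

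Alternatives chosen after seeing the data were the mTERT pairs alone as a block, pairing on all probe sets (mean correlation 0.621 against 0.732), the macrophage mean as a covariate, the splits that part every mTERT pair, with their shares of separate groups, the number of the wild types as a block with its splits, Tert at the background level, and the named list members with 1 array left out. With the covariate 5 mTR, 1 difference and 5 wild-type lists passed, and the mTR calls of cartilage (0.0682), Hox (0.0682) and limb genes (0.0566) were lost. Other offsets before taking logs were not run, since the table was already in log2. Terc lay within background, so signal over background limits any statement on it.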

Other observations

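The test of Terc against background and those of DNA around the targeted genes were planned before the values were seen, while the other splits, the block and the omissions around Tert and the single genes below were chosen after their values were seen. Cultures of the same genotype differed most in immune and positional genes. The median standard deviation within groups was 0.97 for macrophage markers, 0.70 for interferon-stimulated genes, 0.40 for NF-kB targets, 0.40 for senescence genes, 0.32 for limb regulators and 0.31 for Hox genes. Random lists of equal size had medians between 0.12 and 0.14 for these 6. Telomerase genes (0.12), shelterin genes (0.13), DNA damage response genes (0.14) and ribosomal proteins (0.08) varied no more than random lists. Among single genes the neutrophil chemokine Cxcl5 (standard deviation 1.94), the matrix metalloprotease Mmp3 (1.72), the angiotensin receptor Agtr2 (1.55) and the interferon-induced Ifit1 (1.52) varied most along with Egfl6 (1.62) and Lcn2 (1.53).

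In the mTERT line several of these genes followed the pair. Lum, a proteoglycan of collagen matrix, read 8.20, 8.23 and 5.62 in mTERT WT cultures 1 to 3 and 9.03, 10.09 and 6.56 in mTERT KO cultures 1 to 3. Pdgfra, a receptor of mesenchymal cells, read 9.01, 8.83 and 6.31 in wild type and 9.44, 9.43 and 6.21 in the knockout. Saa3, an acute phase gene, was 9.13 and 8.83 in pair 2 and at most 5.70 in the other mTERT cultures. Macrophage markers were above background in all 12 cultures, with Lyz2 at a mean of 12.09. Sftpc, the surfactant protein C gene of lung alveolar epithelium, read 9.17 in mTR WT 1 and at most 4.44 in the other 11 cultures.

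Terc passed the 95th percentile of olfactory receptor probe sets in 0 of 9 cultures with an intact gene, its percentiles running from 70.9 to 93.5, so the mTR label could not be tested by expression.

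A hypothesis was that DNA carried along with each targeted allele changes neighbouring genes, with chance structure of the cultures as the other explanation. Within 10 Mb of Tert 6 probe sets (4.88%) had an unadjusted p below 0.05 in the mTERT comparison, against 1.85% elsewhere (Fisher p = 0.0280), among them Ndufs6, Arsk, Ahrr, Sdha and Cast. The 3 other splits that parted all pairs gave p values of 0.0241, 0.0809 and 0.00883, and the question stayed open. With the mTERT pairs as a block 9 probe sets (7.32% against 2.36%) had such a p (Fisher p = 0.00276), and with 1 array left out the Fisher p ran from 0.00105 without mTERT KO 3 to 0.103 without mTERT KO 2. In the mTR comparison, where Tert is intact, the share near Tert was 7.32%, against 5.96% elsewhere (Fisher p = 0.3125). Ahrr was lower in mTR KO (−0.62), opposite to the mTERT line. Ndufs6 read 6.88, 6.77 and 6.79 in mTR WT and 6.61, 6.61 and 6.64 in mTR KO cultures. For Arsk the mTR groups overlapped. Around Terc 21 of 374 probe sets (5.61%) had such a p in the mTR comparison, against 5.97% elsewhere (Fisher p = 0.645), so the predicted surplus was not seen there. A share over 374 probe sets cannot exclude changes in a few neighbours. The fixed list of Terc neighbours followed the human gene order, and 0 of its 18 genes lay within 10 Mb of Terc in assembly GRCm38.p6.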
